A study of Drosophila melanogaster with 3 samples.

How the data were processed

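Chromatin immunoprecipitation and sequencing of Myc tagged with green fluorescent protein was analysed in 3 biological replicates of whole embryos aged 0 to 16 h, males and females pooled, which form 1 group per the labels. Chromatin was sheared by sonication to fragments of 200 to 800 bp, and an antibody against the tag was used, per the labels. The peak lists in narrowPeak format were used: 1 list per replicate and 1 for the pooled replicates, kept at a relaxed threshold as input for the irreproducible discovery rate (IDR), and 1 list thresholded by IDR. Each exists for the dm6 and the dm3 genome. Per the deposited file listing, relaxed lists were derived from the alignments of a replicate, or of all 3, together with a control file, and the IDR list from the 3 replicates' relaxed lists and the pooled one. The aligner, the peak caller, the IDR threshold and the scaling of the peak scores are not given in the sources used here. The signal value of a peak is the peak caller's own score, as deposited by the authors. The −log10 q value of a peak was computed by the authors' peak caller and deposited in the same lists; 72.3% of dm6 IDR peaks shared its highest value, so it was used only to describe the lists. Summits were taken from the deposited offset within each peak.

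The dm6 IDR list (4371 peaks) was the main peak set, and the lists of replicates 1, 2 and 3 held 29853, 26058 and 25842 peaks. All dm6 peaks lay on the arms 2L, 2R, 3L, 3R, 4 and X. The dm3 lists had no annotation or genome to go with them here and served for counts and overlaps only. Read counts were not used here, so the depth of each library is unknown; 95% Wilson intervals over peaks or genes cover counting error only, and the spread between replicates is given as SD with n = 3. Signal tracks, alignments and control samples were not analysed here.

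Genes and transcription starts came from Ensembl release 115 (annotation BDGP6.54) and sequences from the dm6 genome; peak ends were checked against the arm lengths. A promoter was 500 bp each side of any start of a protein-coding gene, and a gene was called bound when an IDR summit lay in that window. Each summit was placed in the first class that applied: promoter, untranslated region or coding exon, intron, intergenic. For replicate values, the strongest 4371 peaks of each relaxed list (the top list) were treated in the same way. A summit counted as shared when another lay within 100 bp, and overlap by chance was estimated from 100 seeded rotations of the summits along each arm. The relative signal of a peak is its signal in a replicate divided by the median over the IDR peaks found in that replicate. Spearman's rho of signal was taken across peaks, which are not independent replicates.

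The share of summits in promoters, and near (within 250 bp of) tRNA and snoRNA genes, was compared with the share of bases by an exact binomial test. A p-value too small to be stored was written as its upper limit, 1e-300. DNA words were searched on both strands within 50 bp of a summit and in 1 control window per peak of the same width, 500 bp to a side drawn at random with a fixed seed, by an exact McNemar test adjusted over 11 words, 3 of them control palindromes. For genes without a promoter peak the window was centred on the outermost start. The strongest and weakest 1092 peaks by signal, and the promoter peaks of each gene list against all others, were compared by Fisher's exact test. The bound share of 21 gene lists was compared with all other protein-coding genes by Fisher's exact test, and that of 6 arms likewise. All tests were two-sided. Tests of words, gene lists and arms were adjusted within each family by the Benjamini-Hochberg method with a threshold of 0.05, and the binomial tests of promoters, tRNA and snoRNA genes were not adjusted.

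Lists, words, comparisons and alternatives were fixed before the data were examined. Lists were defined by gene symbols or symbol patterns. Older symbols were matched through synonyms (dm is Myc, h is hry, nos is nanos), and the names Nol9, Bop1 and Miz1 matched no gene. The snoRNA host genes are non-coding, and their starts were compared with those of protein-coding genes, a choice made when the annotation was read. The pattern for chorion genes also took in Cp110 and Cp190, which code for centrosomal proteins, so an alternative without them was added after seeing the data. The genes eIF6 and nanos each count in 2 lists. Named genes were chosen by rule: the 10 genes nearest the strongest promoter peaks present in all 3 top lists, the 3 bound members of each list with the highest signal, 15 genes fixed by name (among them Myc, Max, Mnt, CycE and stg), and the 5 strongest peaks outside promoters. One gene that the rule names is not reported here. Genes named beyond this rule were chosen after their values were seen: wg, RpS5a, RpS10b and Uhg8, the unbound members listed with each group, and the genes of the closing section.

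Alternatives were the stronger part of the IDR list by signal, leaving out each replicate, peaks in all 3 top lists only, promoter windows of 250 and 1000 bp, overlap of the whole peak, each peak given to its nearest start, a background of genes with a pooled relaxed summit at a promoter, other word windows (25 and 100 bp) and controls, other orderings and group sizes for signal, other rules of overlap between replicates, and the dm3 lists. Leaving out a replicate meant keeping the IDR peaks found in the top lists of both others, since the IDR list itself could not be remade. The nearest-start rule was not applied to the snoRNA host genes. The tests of gene lists, words and promoter share were tested on simulated data with known answers before use. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.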

Results

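Binding of Myc, the basic helix-loop-helix transcription factor encoded by the fly gene diminutive (dm, current symbol Myc, FBgn0262656), was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos. The embryos were of both sexes and aged 0 to 16 h. The flies carried a transgene coding for Myc with green fluorescent protein at its C terminus, and chromatin was precipitated with an antibody against that tag. Myc pairs with Max and recognises E-box sequences, the canonical one being CACGTG. The samples form 1 group of 3 biological replicates, so the comparisons are between genes, gene groups and positions in the genome, and between replicates. The deposited lists hold peaks and no read counts, so the depth of each library is unknown here.

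The list thresholded for irreproducible discovery rate (IDR), which keeps peaks ranked alike in different replicates, held 4371 peaks on the main chromosome arms of the dm6 genome. Their deposited signal values, the authors' own score for each peak, had a median of 176 and reached 2067. Of these peaks, 2244 (51.3%, 95% Wilson interval 49.9 to 52.8%) had a summit within 100 bp of one in the top list of each of the 3 replicates. A top list holds the 4371 strongest peaks of a replicate. In at least 2 top lists, 83.0% of IDR peaks had such a summit. No IDR peak was shared by all 3 top lists in any of 100 random rotations of the summits along their arms. Since the IDR list was derived from these same replicates, overlap with them is partly built in, and the rotations are no independent test of agreement. Single top lists contained 77.7% ± 3.38 (SD, n = 3) of the IDR summits. Whole relaxed lists, which keep weak peaks and held 27251 ± 2256 peaks (SD, n = 3), contained 94.8% ± 1.61 (SD, n = 3). Across IDR peaks, which are not independent replicates, Spearman's rho of the signal was 0.701 between replicates 1 and 2, 0.582 between 1 and 3 and 0.526 between 2 and 3.

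Myc peaks lay at promoters. Of the 4371 IDR summits, 2991 (68.4%, Wilson interval 67.0 to 69.8%) fell within 500 bp of a transcription start of a protein-coding gene. These windows cover 11.5% of the main arms, which makes a 5.97-fold excess (exact binomial test, two-sided, p below 1e-300). In the 3 top lists the share was 67.6% ± 4.96 (SD, n = 3), with replicate 3 at 61.9% below replicates 1 (70.8%) and 2 (70.1%). The median summit lay just upstream of the nearest start (-26 bp, quartiles -97 and 28 bp). Of the promoter peaks, 1187 (39.7%) had starts of 2 or more genes in reach, and below such sharing is not stated for every gene named. Introns away from promoters held 904 summits (20.7%, against 39.3% of bases) and intergenic sequence 412 (9.43%, against 30% of bases), whereas coding exons held 17 (0.389%, against 13.9%). In all, 3619 of 13945 protein-coding genes (26.0%) had an IDR summit at a promoter, called bound below, and the 3 top lists gave 3509 ± 153 genes (SD, n = 3).

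**Figure D1:**
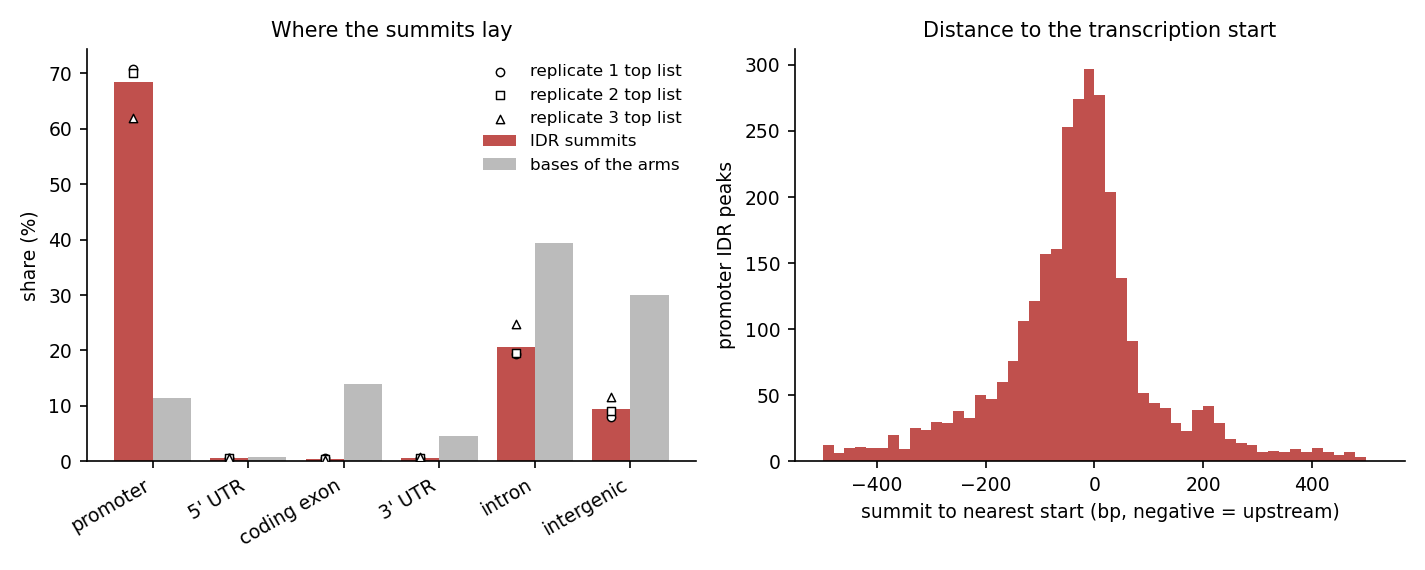
Left, share in percent of the 4371 IDR summits (red bars), of each replicate's top list (open symbols) and of the bases of the main arms (grey bars) in each class of annotation; right, number of promoter IDR peaks by distance in bp from the summit to the nearest protein-coding start, in bins of 20 bp. Promoters hold 68.4% of IDR summits and 11.5% of bases, and the summits centre just upstream of the start.

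The strongest promoter peaks included ribosomal protein genes and Fib. To compare replicates, the signal of a peak in each was divided by the median over the IDR peaks found in that replicate, and this relative signal is given as a mean over replicates. At RpL11 (2R, peak 19442079 to 19442512), which codes for a large-subunit ribosomal protein, the summit lay just upstream of the start (-53 bp), with a signal of 1791 and a relative signal of 9.77 ± 1.85 (SD, n = 3). Fib, the gene of fibrillarin, the methyltransferase of nucleolar box C/D particles, had its summit closer to the start (-15 bp; 2R, peak 23074485 to 23074969, shared with CG3085), a signal of 1736 and a relative signal of 9.61 ± 1.83 (SD, n = 3). RpL7, RpL14 and RpL41, which share their peaks with Ripalpha, Nelf-E and NaCP60E, followed with signals of 1577, 1519 and 1449. The other 5 of the 10 strongest were CG14100 (2033), the nucleotide-sugar transporter gene Ugalt (1765), px (1705), vig (1688) and the methyltransferase gene Art3 (1687), whose peak also served mRpS10. Of the 10, RpL11, Fib and RpL7 held CACGTG within 50 bp of the summit.

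**Figure D2:**
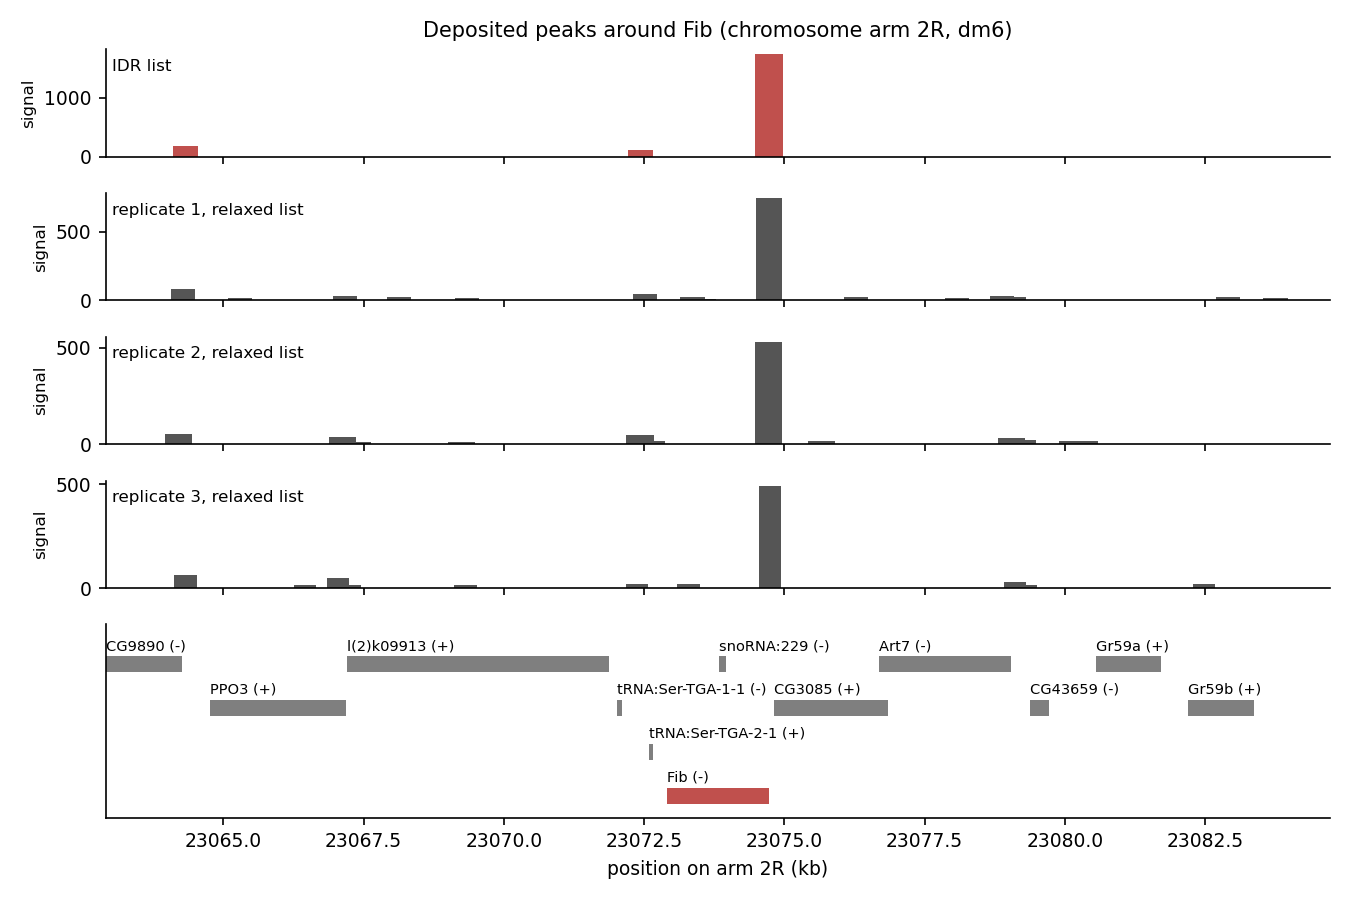
Deposited dm6 peaks around Fib on arm 2R: each bar spans a peak (position in kb) and its height is the deposited signal, in the IDR list (red) and in the relaxed list of each replicate (grey), above the annotated genes with their strands. The peak at the Fib start, with a signal of 1736 in the IDR list, is the highest of the region in all 4 lists.

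Some of the highest peaks lay outside promoter windows. The highest of the whole list (signal 2067, relative signal 11.1 ± 2.82, SD, n = 3) was in an intron of ush at 2L, 480876 to 481299, with the nearest coding start, at -1369 bp, that of cbt, a transcription factor gene. The next was in an intron of CG11050 at 2L, 6612454 to 6612947 (signal 1608, 8.65 ± 1.74, SD, n = 3), and the third in an intron of Lk6, a kinase gene, at 3R, 11760861 to 11761226 (signal 1323, 7.11 ± 2.31, SD, n = 3), at -969 bp from its nearest start. The remaining pair was intergenic with respect to coding genes: X, 12751135 to 12751624 (signal 1219), within the long non-coding RNA gene Vinr, and 2R, 13035141 to 13035525 (signal 1217). All 5 were in the top lists of all 3 replicates, and none held CACGTG within 50 bp of the summit. Promoter peaks had a median signal of 186, intronic peaks 161 and intergenic peaks 162.

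CACGTG was found at 263 of the 4371 IDR summits (6.02%, Wilson interval 5.35 to 6.76%), within 50 bp. It was found in 74 control windows (1.69%) placed 500 bp to one side (exact McNemar test, two-sided, adjusted p = 2.0e-26 over 11 words). In the 3 top lists the share was 6.12% ± 1.22 (SD, n = 3). The variant boxes CACGCG (5.28% against 2.75%, adjusted p = 3.7e-09), CATGTG (7.41% against 4.60%, adjusted p = 5.0e-08) and CAGCTG (7.12% against 4.90%, adjusted p = 1.8e-05) were also more frequent at summits (same exact test). By fold over the control windows, the largest excesses belonged to words of core promoters: TATCGATA, the site of the DNA replication-related element factor DREF, at 4.71% against 0.389% (adjusted p = 6.3e-42), and GGTCACAC, the core of Motif 1, at 3.68% against 0.320% (exact McNemar test, adjusted p = 1.3e-32). Around the starts of the 10326 genes without a Myc promoter peak, TATCGATA was found at 3.68% and GGTCACAC at 4.01%, whereas CACGTG was found at 0.901%. The shares above include summits outside promoters. At promoter IDR peaks alone, TATCGATA was found at 6.75%, GGTCACAC at 5.22% and CACGTG at 6.85%, in windows centred on the summit and not on the start. The Zelda word CAGGTAG (0.480% against 0.732%, adjusted p = 0.197) and the GAGA factor word GAGAGAG (2.36% against 2.24%, adjusted p = 0.775) did not pass the same exact test. Of 3 palindromes taken as controls, AGCGCT did not pass the test (2.10% against 1.83%, exact McNemar test, adjusted p = 0.433), TCCGGA was rarer at summits (0.778% against 1.90%, adjusted p = 8.8e-06) and GTGCAC was more frequent (4.05% against 1.72%, adjusted p = 2.1e-10). An excess of the size seen for the variant boxes also occurred for a word chosen as a control.

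CACGTG was concentrated in the strongest peaks. It was present at 146 of the 1092 strongest peaks (13.4%, Wilson interval 11.5 to 15.5%) and at 39 of the 1092 weakest (3.57%, interval 2.62 to 4.84%), an odds ratio of 4.17 (Fisher's exact test, two-sided, p = 5.5e-17, adjusted p = 6.0e-16 over the 11 words). With the list divided into 10 parts by signal, the share was 19.2% (interval 15.8 to 23.1%) in the 438 strongest peaks, 10.8% in the next 437, and between 2.75 and 4.12% in parts 5 to 10. None of the other 10 words passed the test between the strongest and the weakest 1092 peaks after adjustment; the smallest adjusted p was 0.135, for TATCGATA (5.68% against 3.57%, Fisher's exact test). Leaving out replicate 1, 2 or 3 gave odds ratios of 8.55, 7.05 and 3.90.

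**Figure D3:**
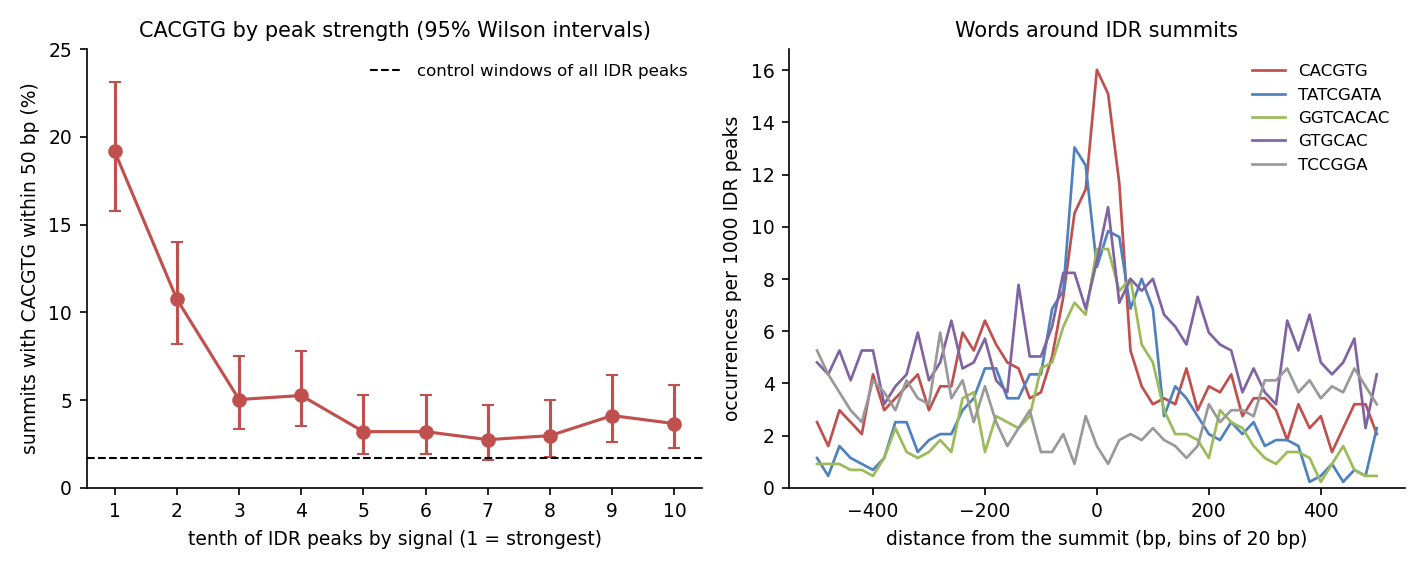
Left, percentage of IDR summits with CACGTG within 50 bp in each of 10 parts of the list ordered by signal (points, with 95% Wilson intervals), and in the control windows of all IDR peaks (dashed line, 1.69%); right, occurrences per 1000 IDR peaks of 5 words by distance in bp from the summit, in bins of 20 bp. The share falls from 19.2% in the strongest part to 3.66% in the weakest, and CACGTG rises at the summit, as the control palindrome GTGCAC does less sharply and the control palindrome TCCGGA does not.

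Binding was most complete in the list of ribosome biogenesis and nucleolus genes, a set chosen by symbol and not a full annotation. All 34 genes of the ribosome biogenesis and nucleolus list had a promoter peak, against 25.8% of other genes (Fisher's exact test, two-sided, adjusted p = 7.5e-20 over 21 lists), and 99.0% ± 1.70 (SD, n = 3) did in the single top lists. Their peaks were strong, with a median signal of 669 against 184 at other promoter peaks, and many held CACGTG. Of the 34 peaks, 22 (64.7%, Wilson interval 47.9 to 78.5%) did, against 6.19% elsewhere (odds ratio 27.8, Fisher's exact test, adjusted p = 4.1e-17). After Fib, the highest were Nopp140, a nucleolar phosphoprotein gene (3L, peak 21832555 to 21833013, signal 1189, relative signal 6.60 ± 1.04, SD, n = 3), and nop5, a core box C/D protein gene (2L, peak 6918516 to 6918931, signal 1160, 6.34 ± 1.72, SD, n = 3), both with CACGTG. Nop60B, the pseudouridine synthase of box H/ACA particles (908, a peak shared with mRpS17), ppan (586) and the helicase gene pit (476) also carried it. The non-coding snoRNA host genes were bound too: 6 of 7 had a peak at the start (odds ratio 17.1 against protein-coding genes, Fisher's exact test, adjusted p = 0.00292), with signals from 369 at Uhg8 to 585 at Uhg4, and CACGTG was present at 5 of them. Uhg7 had none.

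Most cytosolic ribosomal protein genes were bound too. Of 88 cytosolic ribosomal protein genes, 82 (93.2%) were bound (odds ratio 39.9, adjusted exact p = 9.2e-40), with a median signal of 497. Of these 82 peaks, 13 (15.9%) held CACGTG, against 6.60% of other promoter peaks (odds ratio 2.67, Fisher's exact test, adjusted p = 0.0286). The 6 without a peak were RpL38 and 5 copies, RpS5b, RpS10a, RpS19b, RpL10Aa and RpL37-2, named after their values were seen. The partner of each of these copies was bound, as RpS5a with a signal of 575 and RpS10b with 567. Of 21 RNA polymerase I and III genes 17 were bound (odds ratio 12.2, adjusted exact p = 7.3e-07), led by Bdp1, a subunit of the polymerase III initiation factor (2L, peak 13373667 to 13374272, shared with CG6565, signal 1102, relative signal 5.97 ± 0.740, SD, n = 3), and Polr1E (940). Of the 17 peaks, 5 held CACGTG (29.4%, Fisher's exact test, adjusted p = 0.0286). The polymerase I initiation factor gene Tif-IA had a weaker peak (signal 145, relative signal 0.794 ± 0.242, SD, n = 3), outside at least 1 of the 3 top lists.

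Other parts of the translation and growth machinery followed. Translation factor genes were bound in 37 of 53 cases (odds ratio 6.66, adjusted exact p = 1.1e-10), with eEF5 (2R, peak 24057587 to 24057969, signal 1139), eIF6 (1100) and eEF1alpha1 (953) highest. None of their 37 peaks held CACGTG, which did not pass the test against other promoter peaks (6.94%, Fisher's exact test, adjusted p = 0.670). Aminoacyl-tRNA synthetase genes were bound in 21 of 35 cases (odds ratio 4.30, adjusted exact p = 4.5e-05), with GlnRS (1046, shared with RIOK2), SerRS (519) and IleRS (427) highest. The chaperonin and chaperone list had 13 of 16 members bound (odds ratio 12.4, adjusted exact p = 1.4e-05), among them Hsc70-4 (519), Hsp83 (511) and CCT7 (423). Mitochondrial ribosomal protein genes were bound in 39 of 73 cases (odds ratio 3.30, adjusted exact p = 1.8e-06), the strongest peaks being at mRpS10 (1687), mRpL41 (1146) and mRpS23 (1059). That list lost its call when each peak was given to its single nearest start (odds ratio 1.19, Fisher's exact test, adjusted p = 0.608) and when only genes with a relaxed pooled promoter peak formed the background (odds ratio 1.51, adjusted p = 0.165).

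Replication and cell cycle genes were bound in 23 of 35 cases (odds ratio 5.50, adjusted exact p = 2.3e-06), with modest signals (median 163). The highest were at Orc2, a subunit of the origin recognition complex (3R, peak 13964485 to 13964810, signal 765, shared with Kots), Mcm5 of the replicative helicase (456, shared with Art1) and the E2F partner gene Dp (286). CycE and stg, which drive entry into S phase and mitosis, had no promoter IDR peak. Also enriched were the lists of glycolysis (7 of 12, odds ratio 4.00, adjusted exact p = 0.0242, with Gapdh2 at 428 and Hex-A at 335), the proteasome (15 of 32, odds ratio 2.52, adjusted p = 0.0201, with Prosbeta1 at 744, a peak shared with Rrp42) and oxidative phosphorylation (28 of 68, odds ratio 2.01, adjusted p = 0.0125, with COX5A at 436). Against the relaxed background none of these 3 kept its call (odds ratios 1.89, 1.25 and 1.12, adjusted exact p = 0.489, 0.646 and 0.721), and among the 2185 strongest peaks the replication and cell cycle list lost its call too (odds ratio 2.23, adjusted p = 0.0877). When replicates were left out, which also lowers the bound share of other genes, the odds ratios stayed above 1. The calls were lost for the proteasome without any 1 replicate (odds ratios 1.93 to 2.15), for oxidative phosphorylation without replicate 1 (1.70) or 3 (1.79), and for glycolysis without replicate 1 (3.37).

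Myc peaks were also found at genes of its own network. Of 14 network and cofactor genes 11 were bound (odds ratio 10.5, adjusted exact p = 1.1e-04). The peaks of the transcription factors themselves were weak: Myc (X, 3372972 to 3373421) had a signal of 160 and a relative signal of 0.891 ± 0.452 (SD, n = 3), and its partner Max (3L, 19264158 to 19264607, shared with CG42374 and Mettl5) 130 (0.770 ± 0.146, SD, n = 3). The Myc peak lay outside at least 1 of the 3 top lists. Mnt, which competes with Myc for Max (X, 3687821 to 3688270), had a signal of 154 (0.821 ± 0.152, SD, n = 3), with CACGTG in the peak. Higher were the cofactor genes rept (3L, 19255208 to 19255425, signal 535, shared with mRpL21, relative signal 2.98 ± 0.675, SD, n = 3) and brm (276, 1.54 ± 0.452, SD, n = 3) and the gene of the Max-like protein bigmax (347, 1.91 ± 0.266, SD, n = 3). Mondo (116) and pont (172) were bound, each outside at least 1 of the 3 top lists, and Hcf, ago and Nipped-A were not bound. Among the 2185 strongest peaks, the network list was no longer called (odds ratio 1.52, adjusted exact p = 0.509).

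Of 8 lists of tissue-restricted genes, 6 were bound less often than other genes, while muscle and germline genes did not pass the test. Genes of the chemosensory receptor list, whose patterns also took in odorant-binding protein (Obp) genes, were bound in 4 of 230 cases (odds ratio 0.0494, Fisher's exact test, adjusted p = 1.8e-23). Cuticle genes were bound in 1 of 117 cases (odds ratio 0.0243, adjusted exact p = 1.5e-13), that one being Lcp9, whose start lay far from the summit (-465 bp, signal 842), in a peak shared with CG3594. Few members of either list had even a relaxed pooled promoter peak. Among chemosensory genes that had one, 4 of 21 were bound (odds ratio 0.253, Fisher's exact test, adjusted p = 0.0186). Among such cuticle genes, 1 of 14 was bound (odds ratio 0.0828, Fisher's exact test, adjusted p = 0.00598). Embryonic patterning genes were bound in 4 of 40 cases (odds ratio 0.316, adjusted exact p = 0.0242). These were the maternal genes nanos (392) and bcd (163), the pair-rule gene hry (126) and the signalling gene wg (113). The nanos start lay far from the summit (-405 bp), in a peak shared with CG11779. Neuron and glia genes were bound in 2 of 25 cases (odds ratio 0.248, adjusted exact p = 0.0441, elav at 359 and Csp at 240). Blood cell genes were bound in 0 of 14 cases (Wilson interval 0 to 21.5%, adjusted exact p = 0.0325). This counts promoters only, and ush of that list held the highest IDR peak (signal 2067) in an intron. Chorion and yolk genes were bound in 1 of 21 cases (odds ratio 0.142, adjusted exact p = 0.0294), the one being Cp190, a centrosome and insulator protein taken in by its symbol. Muscle genes (4 of 23, adjusted exact p = 0.501, Msp300 at 489 and Tm1 at 415) and germline genes (5 of 19, adjusted p = 1, bgcn at 416) did not pass the test. The calls for neurons and glia, blood cells and chorion and yolk were lost when any 1 replicate was left out, and that for embryonic patterning without replicate 2 (odds ratio 0.343, adjusted exact p = 0.0962). All 4 of these calls were also lost when each peak was given to its single nearest start (embryonic patterning: odds ratio 0.342, adjusted exact p = 0.111).

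**Figure D4:**
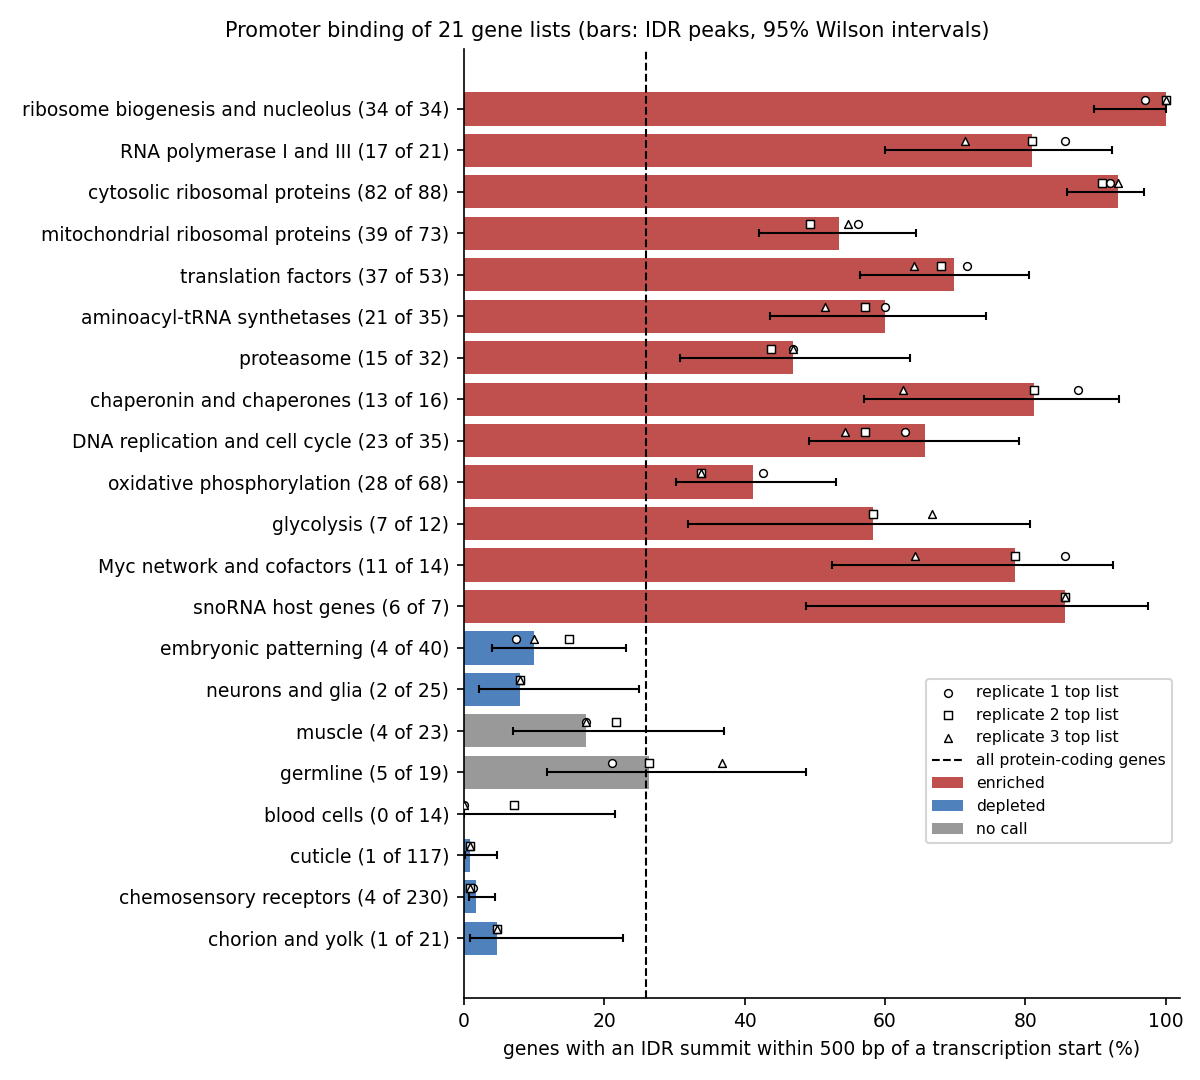
Percentage of genes in each of 21 lists with an IDR summit within 500 bp of a transcription start (bars, with 95% Wilson intervals and counts in the labels), coloured by call at an adjusted p of 0.05, and the same percentage from each replicate's top list (open symbols); the dashed line is the share of all protein-coding genes (26.0%). The share runs from 100% for ribosome biogenesis to 0% for blood cell genes, with 13 lists enriched and 6 depleted.

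Summits were more frequent near snoRNA genes than the bases covered would give, and tRNA genes did not pass the same test. Summits within 250 bp of a snoRNA gene numbered 21 against 3.76 expected from the bases covered (5.59-fold, exact binomial test, two-sided, p = 6.3e-10), and reached 21 of 269 snoRNA genes. That excess was no larger than the one of promoters over their bases (5.97-fold), and snoRNA genes lie in introns of host genes. Summits at host promoters were not set apart from summits at the snoRNA genes themselves. Near tRNA genes there were 6 summits against 4.65 expected (p = 0.480, exact binomial test), at 6 of 290 genes. In the top lists, snoRNA genes took 0.488% ± 0.0803 and tRNA genes 0.183% ± 0.0229 of summits (SD, n = 3). On the 5 large arms, bound promoters made up from 24.8% of genes on 2L to 27.4% on 3R, and none of the 6 arms passed the test after adjustment. Chromosome 4, with 12 of 80 genes bound (15%, Fisher's exact test, adjusted p = 0.0862), and 3R (adjusted p = 0.0862) came nearest.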

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

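This part reports counts only, and no test was run on them. The dm3 lists, which no comparison of the report uses beyond counts and overlaps, held peaks on sequences outside the main arms, where the dm6 lists held none: 37 in the pooled relaxed list, and 59, 61 and 100 in those of replicates 1, 2 and 3, above the limit of 3 that a count of 0 allows. In replicate 3 these were 0.464% of the list, most of them on the heterochromatic sequences 2RHet (30), 3LHet (24) and 3RHet (20). The dm3 IDR list held 3 such peaks, 2 on 3LHet and 1 on U. The off-arm sequences of dm3 were not traced into dm6, so these counts do not show that peaks were gained or lost between the builds. No control level was used here, no dm3 sequence or annotation was used to place the peaks near genes, and no explanation was tested.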

How the results depend on the processing

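The chorion and yolk list without Cp110 and Cp190 was the one alternative chosen after seeing the data. Of 273 alternatives, 212 left a tested result on its side of the threshold or a count within 1.5 times its main value, 49 ended the call of a gene list without turning its direction, 12 moved a count and 0 reversed one. The promoter share (61.1 to 75.3%), the CACGTG share (3.43 to 8.70%) and its odds ratio between strongest and weakest peaks (3.65 to 8.55) stayed past the threshold under each alternative run. So did ribosome biogenesis, RNA polymerase I and III, cytosolic ribosomal proteins, translation factors, synthetases, chaperones, snoRNA hosts, cuticle and chemosensory receptors. The nearest-start setting did not reassign peaks for the snoRNA hosts, so their bound count could not change there.

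Counts moved where the alternative kept fewer peaks or counted more: 2185 IDR peaks in the stronger part of the list, with 2125 bound genes; 2243 bound genes for peaks in all 3 top lists; and 3767 IDR peaks shared by whole relaxed lists or 1190 by top lists shortened to 2185 peaks, against 2244. Depleted lists numbered 3 in the stronger part, 3 for peaks in all 3 top lists, 2 with the nearest start, 3 with the relaxed background and 2 to 3 when a replicate was left out, against 6.

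Gene lists that lost their call had these bound shares and, in brackets, odds ratios against other genes, whose own share changes with the setting. Stronger part: proteasome 25% (1.86), replication and cell cycle 28.6% (2.23), oxidative phosphorylation 22.1% (1.58), Myc network 21.4% (1.52), neurons and glia 8% (0.483), blood cells 0% (0), chorion and yolk 4.76% (0.278). Peaks in all 3 top lists: proteasome 28.1% (2.05), oxidative phosphorylation 25% (1.74), neurons and glia 8% (0.453), blood cells 0% (0), chorion and yolk 4.76% (0.261). Window of 250 bp: glycolysis 41.7% (2.49), blood cells 0% (0), chorion and yolk 4.76% (0.174); of 1000 bp: glycolysis 58.3% (3.45), blood cells 7.14% (0.189), chorion and yolk 9.52% (0.258). Overlap of the whole peak: blood cells 7.14% (0.204). Nearest start: mitochondrial ribosomal proteins 21.9% (1.19), proteasome 31.3% (1.93), oxidative phosphorylation 23.5% (1.3), patterning 7.5% (0.342), neurons and glia 8% (0.367), blood cells 0% (0), chorion and yolk 4.76% (0.211). Relaxed background, where about 48.0% of other genes are bound: mitochondrial ribosomal proteins 58.2% (1.51), proteasome 53.6% (1.25), oxidative phosphorylation 50.9% (1.12), glycolysis 63.6% (1.89), neurons and glia 16.7% (0.215), blood cells 0% (0), chorion and yolk 33.3% (0.540).

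Leaving out a replicate gave proteasome 31.3% each time (1.93 to 2.15), oxidative phosphorylation 26.5 to 30.9% (1.70 to 1.90; call lost without replicates 1 and 3), glycolysis 41.7 to 50% (3.37 to 4.30; lost without 1), patterning 2.5 to 7.5% (0.110 to 0.343; lost without 2), and each time neurons and glia 8% (0.368 to 0.410), blood cells 0% (0) and chorion and yolk 4.76% (0.212 to 0.235). Leaving out a replicate or peaks lowers the share of bound genes by construction, which leaves less room for a depletion to be called. Beyond that the cause was not tested, and a lost call does not show that the difference was gone. Without Cp110 and Cp190, 0 of 19 chorion and yolk genes were bound (Fisher's exact test, adjusted p = 0.0104). No paired analysis was possible because there was 1 group. Without read counts, what depth limits could not be measured.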

Other observations

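Chosen only after their results were seen were the comparisons of gene families, synthetases, ribosomal protein copies and 6-base words, the test of GTGCAC outside promoters, and the promoter share among peaks of replicate 3 shared with the other replicates. Among protein-coding genes outside the 21 lists, 60 families sharing a symbol prefix with at least 10 members were tested against all other genes (Fisher's exact test, two-sided, adjusted over 60), and 4 were bound more often and 10 less often. The nucleoporin genes were bound in 15 of 21 cases (71.4%, odds ratio 7.16, adjusted exact p = 3.3e-04), with Nup37 (signal 1115), Nup98-96 (544) and Nup160 (494) highest. The families were not tested with the nearest start only, so peaks named here may also serve neighbouring genes. Genes of the PIG family, which build the glycolipid anchor of surface proteins, were bound in 12 of 21 cases (adjusted exact p = 0.0313, PIG-F at 520). Ubiquitin-specific protease genes were bound in 9 of 15 cases (adjusted exact p = 0.0322, Usp10 at 310). Genes with the prefix Polr outside the polymerase I and III list were bound in 8 of 13 (adjusted exact p = 0.0332, Polr2F at 912 and Polr2H at 540). Whether these subunits serve polymerase II alone was not examined. Bound less often were cytochrome P450 genes (2 of 85, adjusted exact p = 1.7e-07), seminal fluid genes of the Sfp family (0 of 28, adjusted p = 0.00431), ppk sodium channel genes (0 of 29, adjusted p = 0.00431) and histone genes (2.61%, adjusted p = 1.3e-09), the last being repeated copies in which reads are hard to place, a limit not tested here.

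Within the lists, binding differed between compartments and between copies. Of the synthetase genes, 17 of 20 not named as mitochondrial were bound (85%) and 4 of 15 named as mitochondrial (26.7%, odds ratio 15.6, Fisher's exact test, p = 0.00123). Of 9 pairs of ribosomal protein copies, 5 had 1 copy bound and 4 had both, as RpL34b (signal 1288) and RpL34a (461). The 437 strongest peaks and the other 3934 were compared for 2080 words of 6 bases. After adjustment over 2080, 6 words were more frequent and 2 less frequent in the strongest. CACGTG came first (19.2% against 4.55%, Fisher's exact test, adjusted p = 3.1e-21). ACACGT, ACGTGC and ACGTGG, also more frequent, overlap CACGTG in sequence and may count the same sites. GAGAGA was rarer (1.14% against 5.64%, Fisher's exact test, adjusted p = 0.00256).

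The excess of growth gene lists among bound promoters was weighed against 2 technical explanations. If peaks were called at any accessible promoter, few lists would stay enriched against genes with a relaxed pooled summit at a promoter; 9 of the 13 did, between the bounds set beforehand (6 and 10), so this could not be decided. The relaxed list, which keeps weak peaks, is no measure of accessibility, and no accessibility or mock track was used here. Peaks borrowed from neighbouring genes were weighed with the nearest start only, and 10 of 13 lists stayed enriched. The snoRNA host list, among these 10, was not reassigned in that setting, so its bound count could not change. Leaving it aside puts the count below the bound of 10, so this could not be decided for the lists as a whole. The other lists that stayed enriched kept their calls with each peak given to its nearest start. Borrowed peaks stay open for the 3 lists that lost their calls: mitochondrial ribosomal proteins (odds ratio 1.19, from 3.30), oxidative phosphorylation (1.3, from 2.01) and the proteasome. The proteasome's odds ratio of 1.93 (from 2.52) was close to those when a replicate was left out (1.93 to 2.15). That likeness cannot tell borrowed peaks from a general fall in bound genes, so no conclusion is drawn from it. No biological explanation was tested, as the design has 1 group.

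The control palindrome GTGCAC was more frequent at summits than beside them. Sharing peaks with CACGTG was argued against, since the fold was 2.08 among the 4108 peaks without CACGTG (exact McNemar test, p = 9.6e-08). Base composition as the whole cause was argued against too, since it would raise all palindromes with the same bases: the median fold of the other 22 was 0.810, although 3 of those folds had been seen when the bound was set. They went both ways, and GCTAGC (2.21-fold, exact McNemar test, adjusted p = 3.3e-05) and CAGCTG (1.45-fold, adjusted p = 5.3e-05) were also more frequent at summits. Promoter sequence in general was argued against by a fold of 2.15 among the 1380 summits outside promoters (exact McNemar test, p = 0.00105). What stays open is which factor, if any, the word serves, and no biological explanation was tested.

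Replicate 3 had a lower promoter share than replicates 1 and 2. Its summits outside promoters lay near relaxed summits of both other replicates in 73.9% of cases, a difference of 0.919 percentage points from the mean of replicates 1 and 2 (74.7 and 71.4%), but its promoter summits did so in 79.9%, against 78.0 and 73.1% in replicates 1 and 2, and its partners had the longer relaxed lists. Among peaks shared with both other replicates, the promoter share was still 63.7% in replicate 3, against 71.7 and 70.6%, which argues against peaks found in that library alone as the whole cause. In the 1000 strongest peaks its promoter share was 70.7%, against 82.2 and 80.6% (-9.9 percentage points from the lower), which argues against the length of the ranked list as the cause. Other technical differences between the libraries were not tested, and no biological explanation was tested.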
